A study of Mus musculus with 4 samples.

How the data were processed

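Total RNA of sorted OT-I CD8 T cells was measured on Illumina bead arrays in 4 groups: unimmunized (naive) controls, and cells from mice given heat-killed (HKL), irradiated (IRL) or live actA-mutant Listeria monocytogenes (live LM). Per the labels, RNA was extracted with Qiagen RNeasy columns and biotin-labelled by the Eberwine protocol, and each sample stands for 2 arrays. The deposited table of single arrays held, per the file headers, a mean bead intensity for each probe and array, and its values showed no background subtraction and no normalization between arrays. A detection p-value was deposited beside each intensity, per the file headers. Its steps on each array are those of a share among 822 negative control probes, which are themselves not in the table. The software and its version are not given in the sources used here. The processed table held 1 intensity per group and probe from the authors, with no statement of how it was made. When the single arrays were quantile normalized without background subtraction and averaged on the linear scale, 99% of probes lay within 0.126%, 0.0741%, 0.0857% and 0.0557% of the authors' values for naive, HKL, IRL and live LM. The medians of the 4 processed columns were 190.61, 190.197, 189.344 and 189.585. All sample columns were used (0 left over).

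Arrays were assigned to groups by the group word in the column name. The column names also carry a running number, unique to each array, and a date, with 8 distinct dates in an earlier and a later period. What the dates stand for is not given in the sources used here. The table had 24611 lines, 5 of them blank, and 24606 probes. Of these 20984 were named with 1 symbol by the probe table used here, 1 with several, and 3621 with none; 20968 were matched by Entrez identifier, and 0 symbols were updated. The processed table had 24613 probes, 24606 of them shared.

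Intensities were processed in R 4.3.3 with limma 3.58.1. Background was corrected by a normal-exponential model whose noise was inferred from the detection p-values, an offset of 16 was added, and arrays were quantile normalized and put on the log2 scale. Probes were kept if detected (detection p-value under 0.05) on at least 2 of the 8 arrays, which left 11387, of which 9964 had a gene name. For the 1572 genes with several kept probes the one with the highest mean was used, giving 7982 genes. The 1423 kept probes without a name were tested apart. A linear model with 1 mean per group was fitted to the 8 arrays, with 4 residual degrees of freedom, and variances were moderated across genes (limma's two-sided moderated test, prior degrees of freedom 3.24, prior SD 0.183). All 6 pairs of groups were compared. A gene passed at adjusted p < 0.05 by Benjamini-Hochberg over the genes tested. Values are log2 fold changes with the moderated standard error. Where a gene was undetected on both arrays of the dimmer group, the fold was taken against that group's detection floor and is a lower bound, given without the fitted log2 value.

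Gene lists were tested with camera in limma at a preset correlation between genes of 0.01, two-sided, over 138 tests of 23 lists in 6 comparisons. The lists covered CD8 T cell identity, naive quiescence, early genes of T cell receptor signalling, activation receptors, inhibitory receptors and anergy, effector molecules, effector transcription factors with interleukin-12 and interleukin-2 signalling, the type I interferon response, and the interferon gamma response with antigen processing. Others covered DNA replication, mitosis, ribosome biogenesis, glycolysis, the citric acid cycle with oxidative phosphorylation, nucleotide and one-carbon synthesis, amino acid transport, chaperones, lipid synthesis, apoptosis and homing receptors. Markers of B cells, dendritic cells and macrophages, and neutrophils made up the rest. Of 26 lists fixed, the markers of NK cells (2 measured), of CD4 and regulatory T cells (0) and of red cells and platelets (2) had fewer than 3 measured genes and were not tested. Of the 138 tests 59 passed, 0 passed when the correlation was estimated from the residuals, and 63 passed with fry. For nucleotide and one-carbon synthesis and for ribosome biogenesis the estimates were 0.00385 and 0.00958, below the preset 0.01. Their adjusted p in HKL vs naive still rose to 0.0887 with the estimate. The loss of calls with an estimated correlation therefore does not by itself show correlation between genes.

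The groups, comparisons, tests, lists and the rule for named genes were fixed before the data were examined. Named are the 5 genes with the largest fitted rise and the 5 with the largest fitted fall among those past the threshold whose arrays do not overlap between the groups, leaving out clone and predicted names. Also named are up to 4 members of each list with the largest change past the threshold, and, whatever their result, Cd69, Ifng, Il2, Il2ra, Tnf, Prf1, Tbx21, Eomes, Pdcd1, Il7r, Cxcr3, Myc and Irf4. Gzmb, Ifit1 and Mki67 belonged to the same rule but were not among the genes tested and are not analysed here. Other genes of the rule are not reported here.

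Alternatives fixed in advance were no background correction, an offset of 50, cyclic loess, scaling to the 75th percentile, other detection filters (none, both arrays of a group, or all 8 arrays at a detection limit of 0.01), every probe or the mean of a gene's probes, a variance trend with robust moderation, only the 2 groups compared, leaving out each array, and a fold change of at least 2. An estimated correlation and fry were the alternatives for lists, and the processed values of the authors for named genes. After the data were seen, fits with the period as a block and with the class II score as a covariate were added. This score is the mean log2 value of Cd74, H2-Aa, H2-Ab1 and H2-Eb1 on an array. Values among the arrays of 1 period alone were added as well.

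The pipeline was tested on simulated data in which genes were changed by known amounts. It recovered between 90.9% and 97.0% of 4-fold changes, between 46.3% and 53.7% of 2-fold changes and between 0% and 2.99% of 1.5-fold changes. The changed genes were drawn only from those with a mean well above the detection floor. The shares recovered therefore do not cover genes whose mean lies near it. Between 7 and 12 of 102 to 113 calls were false. The changed list was called in each comparison, and 0 of 40 unchanged lists. The simulated noise was independent between genes, so list calls among genes that vary together were not tested. In the data the estimated correlation was 0.738 for the type I interferon list. Few genes were changed, in both directions alike, so the case where most genes differ was not simulated. Since the comparisons with naive share 2 arrays, their overlap was set beside 20 simulations of unchanged groups against the same naive arrays.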

Results

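Gene expression was measured in OT-I CD8 T cells, which carry a single transgenic receptor for an ovalbumin peptide, after their transfer into mice and immunization with Listeria monocytogenes (LM), a bacterium that lives inside host cells. Per the labels, 1 group was an unimmunized (naive) control, and the others received heat-killed bacteria (HKL), irradiated bacteria (IRL) or live bacteria of an actA mutant strain (live LM). ActA is the surface protein that drives movement inside the host cell and spread between cells. Cells were sorted 24 hours after immunization, and the gate kept cells without MHC class II that carried CD8, the transfer marker CD45.1 and the activation marker CD69. The labels do not say whether naive cells passed the same CD69 gate. Each of the 4 groups was measured on 2 Illumina bead arrays, 8 in all. The mean signal of an array lay between 1324 and 1483 on the 6 arrays of immunized groups, and was 663 and 1082 on naive arrays 1 and 2. Between 39.2% and 42.1% of the probes were detected on an array, and 7982 named genes were tested. The labels give 2 biological replicates per group but do not tie the arrays to them, so the p-values may measure technical spread only. Arrays number 2 per group, which limits the precision of every value.

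Naive and immunized cells lay far apart. The first principal component held 83.2% of the variance over the genes tested and placed the naive arrays at -99.16 and -92.30 and the arrays of immunized groups between 18.85 and 42.89. The second held 6.75% and placed the live LM arrays, at -23.97 and -24.00, below those of HKL (20.37 and 15.67) and IRL (11.70 and 6.80). Across genes, which are not independent replicates, Pearson's r between the 2 arrays of a group was 0.980 for naive, 0.988 for HKL, 0.988 for IRL and 0.993 for live LM. Between naive and immunized arrays it lay between 0.785 and 0.858. The arrays carry dates from an earlier and a later period: both naive arrays, HKL array 1 and IRL array 1 are from the earlier one, and HKL array 2, IRL array 2 and both live LM arrays from the later one. Live LM and naive arrays therefore share no period. Transcripts of MHC class II genes, which mark antigen-presenting cells, also varied within groups: the mean log2 value of Cd74, H2-Aa, H2-Ab1 and H2-Eb1 was 8.57 and 10.43 on naive arrays 1 and 2, 6.62 and 10.17 on HKL arrays, 7.55 and 8.60 on IRL arrays and 9.97 and 9.21 on live LM arrays.

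**Figure D1:**
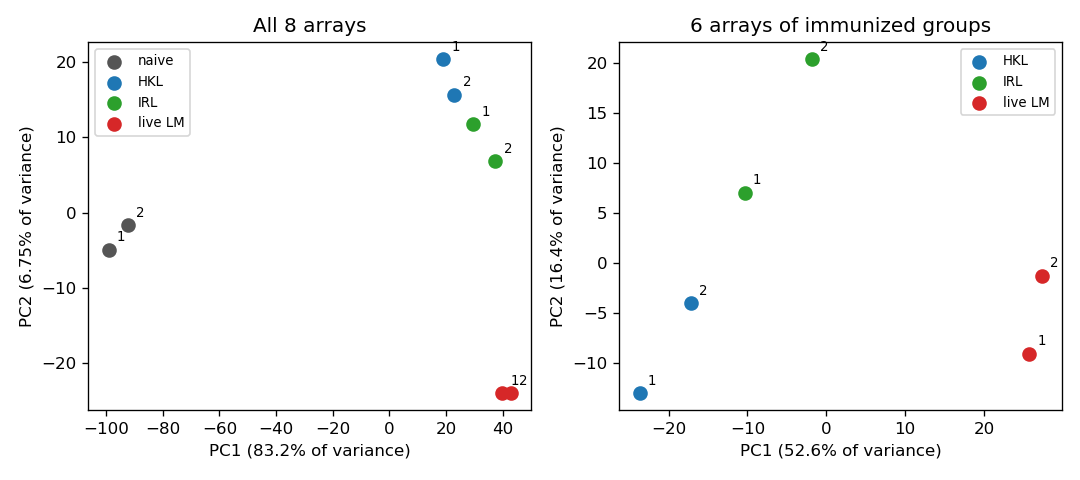
Principal components of the log2 intensities, each point 1 array numbered within its group, for all 8 arrays (left; axes in units of the component, 83.2% and 6.75% of the variance) and for the 6 arrays of immunized groups (right; 52.6% and 16.4%). Naive arrays lie apart at left, and on the right the first component runs from HKL (-23.70 and -17.18) over IRL (-10.35 and -1.82) to live LM (25.70 and 27.35). In HKL and in IRL array 2, from the later period like both live LM arrays, lies nearer to live LM than array 1. This component therefore also runs with the period.

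HKL was compared with naive to see what immunization with killed bacteria changed in the T cells. Ifng, the gene of interferon gamma, rose 99.3-fold in HKL cells (log2 fold change 6.63 ± 0.30, SE, n = 2 arrays per group, adjusted p = 7.12e-06). All 27 tested genes of DNA replication and all 18 of ribosome biogenesis rose. Of 16 genes typical of resting naive T cells, 13 fell. Among them was Il7r, which encodes a chain of the interleukin-7 receptor and was 76.0-fold lower (-6.25 ± 0.50, adjusted p = 5.05e-05). Of the 7982 genes tested, 4798 (60.1%) passed the threshold, 2356 higher and 2442 lower in HKL, and 2818 of these differed at least 2-fold, with genes undetected in the dimmer group taken at their lower bound here and below. Quantile normalization gave all arrays a common distribution, so rises and falls are relative to the other genes in every comparison. The balance of higher and lower genes therefore cannot show a change in total RNA. The arrays of the groups did not overlap for 6270 genes (78.6%), where chance gives 33.3%. An exact permutation test of 2 arrays against 2 cannot go below 0.333.

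The largest measured rises in HKL cells were in the chemokine gene Xcl1 (7.07 ± 0.31), Ifng, Fignl1, whose product acts in recombination repair (6.31 ± 0.33), and the chemokine gene Ccl4 (6.11 ± 0.30). Zbtb32, a zinc finger repressor of transcription, rose at least 153-fold and the thymidine kinase gene Tk1 at least 46.6-fold. The largest measured falls were in Il7r, the transcription factor gene Klf2 (-6.08 ± 0.48), the Fc receptor gene Fcgrt (-5.48 ± 0.21), Pik3ip1, a negative regulator of PI3 kinase (-5.12 ± 0.19), and Cd163l1 (-4.71 ± 0.63). Adjusted p lay between 2.1e-06 and 0.000526 over these genes. "At least" marks folds where the gene was not detected on either array of the dimmer group and the fold was taken against the detection floor. Such folds have no rank among the measured ones. Ifng, Fignl1, Pdcd1, Birc5, Shmt1, Slc1a4, Prc1, Retnlg and Fcer1g were detected on 1 of the 2 naive arrays, and Cd163l1, Tob1 and Ier2 on 1 of the 2 HKL arrays. Il2 (at least 11.1-fold) and its receptor gene Il2ra (at least 11.8-fold) rose. So did the transcription factor genes Irf4 (4.90 ± 0.14), Myc (2.75 ± 0.28), Tbx21 (2.26 ± 0.31) and Eomes (2.10 ± 0.30) and the inhibitory receptor gene Pdcd1 (1.06 ± 0.21). The highest adjusted p of these genes was 0.00361. Prf1, which encodes perforin, fell by 1.44 ± 0.36 (adjusted p = 0.0103). Tnf (0.62 ± 0.34, adjusted p = 0.149), Cxcr3 (0.78 ± 0.43, adjusted p = 0.158) and Cd69 (0.10 ± 0.30, adjusted p = 0.799) did not pass.

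Growth and division genes rose together in HKL cells. The DNA replication list, with Tk1, Rrm2 (at least 39.4-fold) and Cdc45 (at least 35.4-fold), had 27 of 27 genes higher (camera adjusted p = 1.73e-14, adjusted p = 0.0887 with an estimated correlation). In the mitosis list 13 of 18 genes rose, such as Cdk1 (at least 42.4-fold) and Birc5 (5.57 ± 0.22), and 1 fell (adjusted p = 3.92e-06, adjusted p = 0.423 with an estimated correlation). All 18 ribosome biogenesis genes rose, including Nolc1 (2.86 ± 0.25) and Ncl (2.54 ± 0.16, list adjusted p = 3.19e-08, and adjusted p = 0.0887 with an estimated correlation). Of 17 genes of nucleotide and one-carbon synthesis, 16 rose, with Shmt1 at 4.93 ± 0.29 and Umps at 3.84 ± 0.23 (list adjusted p = 7.77e-07, adjusted p = 0.0887 with an estimated correlation). Chaperones and genes of the unfolded protein response rose in 11 of 15 cases, Sdf2l1 by 2.60 ± 0.20, and fell in 1 (adjusted p = 0.000311, adjusted p = 0.247 with an estimated correlation). Glycolysis genes rose in 8 of 12 cases, led by Hk2 (5.13 ± 0.18) and Tpi1 (2.92 ± 0.17), and fell in 2 (adjusted p = 0.0123, adjusted p = 0.534 with an estimated correlation). Of 21 genes of the citric acid cycle and oxidative phosphorylation 13 rose, Fh1 by 1.90 ± 0.13, and none fell (adjusted p = 0.00236, adjusted p = 0.415 with an estimated correlation). With cyclic loess the last call was lost (adjusted p = 0.059). With adjustment inside each list, the counts were 27, 14, 18, 16, 12, 8 and 14 higher in these 7 lists in the order given.

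Transcripts of T cell rest and identity fell in HKL cells. Of 16 naive quiescence genes 13 fell, such as Klf2, Pik3ip1 and Tob1 (-3.71 ± 0.45), and none rose (adjusted p = 6.39e-05, adjusted p = 0.247 with an estimated correlation). Of 11 CD8 T cell identity genes 8 fell, among them the CD3 chain genes Cd3g (-1.74 ± 0.18) and Cd3e (-1.53 ± 0.12), and none rose (adjusted p = 0.0021, adjusted p = 0.471 with an estimated correlation). Homing receptors fell in 6 of 12 cases, with the integrin genes Itgae (-4.67 ± 0.53) and Itgb7 (-4.24 ± 0.17), and rose in 2, and the list as a whole did not pass (adjusted p = 0.143). Genes of the interferon gamma response and antigen processing fell in 11 of 16 cases, such as Irf1 (-2.58 ± 0.24) and Irgm2 (-2.10 ± 0.23), while the transcription factor gene Irf8 rose (4.81 ± 0.31). The list passed at adjusted p = 0.0121, and adjusted p = 0.532 with an estimated correlation. Adjusted over the list alone, 13, 8, 6 and 11 genes were lower in these 4 lists.

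Of 26 type I interferon response genes 12 were lower in HKL cells, such as Ddx58, a sensor of viral RNA (-3.05 ± 0.50), and 9 when adjusted over the list alone (list adjusted p = 0.0241, adjusted p = 0.739 with an estimated correlation). The interferon call was lost without naive array 1 (adjusted p = 0.065), without HKL array 2 (adjusted p = 0.438) and with the period as a block (adjusted p = 0.0725). The list's mean log2 fold change less that of other genes was -1.12 over all arrays and -0.24 among the earlier arrays alone. The lists that follow did not pass in HKL cells. Effector molecules had 7 genes higher, with the chemokine genes Ccl4 and Ccl3 (at least 37.0-fold), and 6 lower of 16 (adjusted p = 0.272). Activation receptors had 7 higher, such as Tnfrsf9 (at least 28.4-fold), and 3 lower of 14 (adjusted p = 0.176). Inhibitory receptors and anergy genes had 5 higher, with Lag3 at least 43.2-fold, and 4 lower, with the diacylglycerol kinase gene Dgka at -4.33 ± 0.25, of 14 (adjusted p = 0.681). Early genes of T cell receptor signalling had 7 higher, such as Irf4, and 8 lower, such as Ier2 (-3.30 ± 0.26), of 20 (adjusted p = 0.939). Effector transcription factors with interleukin-12 and interleukin-2 signalling had 6 higher and 9 lower, Il18r1 at -4.57 ± 0.23, of 19 (adjusted p = 0.776). Apoptosis genes had 4 higher, such as Bcl2l1 (3.23 ± 0.20), and 4 lower, such as Bcl2 (-1.77 ± 0.20), of 15 (adjusted p = 0.855). Amino acid transporters had 5 higher, Slc1a4 by 3.04 ± 0.27, and 1 lower of 7 (adjusted p = 0.11), and lipid and cholesterol synthesis 7 higher and 2 lower of 13 (adjusted p = 0.21). The median and the mean differed in sign for the apoptosis list (-0.19 and 0.26) and the early response list (-0.07, or -0.17 with undetected genes at their bound, and 0.06). For B cell markers the median and the mean were -0.03 and -0.06 while the test ran toward higher values. Within each list alone, higher and lower counts were the same as over all genes in these lists except for the effector transcription factors (7 and 10). Among markers of other cells, 2 of 10 dendritic cell and macrophage genes were lower (adjusted p = 0.414), 0 of 8 neutrophil genes passed (adjusted p = 0.618). In addition, 1 of 7 B cell genes was higher and 1 lower (adjusted p = 0.939). Without naive array 2 the Prf1 call was lost (adjusted p = 0.0532).

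IRL was compared with naive to see what irradiated bacteria changed. Ifng rose 132-fold in IRL cells (7.04 ± 0.30, adjusted p = 4.51e-06) and Klf2 was 93.0-fold lower (-6.54 ± 0.48, adjusted p = 2.76e-05). All 27 DNA replication genes and 17 of 18 mitosis genes rose. All 11 CD8 identity genes fell. Of the genes tested 5072 (63.5%) passed, 2540 higher and 2532 lower, 3109 of them by at least 2-fold. The groups' arrays did not overlap for 6296 genes (78.9%, chance 33.3%).

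Besides Ifng, the largest measured rise in IRL cells was in Xcl1 (6.66 ± 0.31), while Zbtb32 rose at least 211-fold, Cdk1 at least 67.5-fold and the ribonucleotide reductase gene Rrm2 at least 61.9-fold. The largest measured falls were in Klf2, Fcgrt (-6.17 ± 0.21, detected on 1 of the 2 IRL arrays), the steroid enzyme gene Hsd11b1 (-6.04 ± 0.30) and the chemokine gene Ccl5 (-5.73 ± 0.37), and Cd163l1 fell at least 24.3-fold. The highest adjusted p of these genes was 0.000168. Il2 (at least 24.8-fold), Il2ra (at least 21.4-fold), Irf4 (4.82 ± 0.14), Tbx21 (2.47 ± 0.31), Myc (2.07 ± 0.28), Pdcd1 (1.36 ± 0.21) and Eomes (1.29 ± 0.30) rose. Il7r (-5.69 ± 0.50) and Prf1 (-1.55 ± 0.36) fell. The highest adjusted p of these genes was 0.00685. Tnf rose by 0.91 ± 0.34 (adjusted p = 0.0467). This call was lost with the period as a block (adjusted p = 0.131) and on leaving out any array other than naive array 2, with a value of 0.37 without naive array 1 (adjusted p = 0.203). Without naive array 2 the value was 1.45. Prf1 fell by 0.98 without IRL array 1, where it still passed. Cxcr3 (0.73 ± 0.43, adjusted p = 0.179) and Cd69 (0.17 ± 0.30, adjusted p = 0.651) did not pass.

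The same lists of growth genes rose in IRL cells as each was tested there. DNA replication had 27 of 27 genes higher, Tk1 at least 58.1-fold (camera adjusted p = 1.23e-13, adjusted p = 0.0887 with an estimated correlation). Mitosis had 17 of 18, with Prc1 at 6.25 ± 0.33 and Birc5 at 6.20 ± 0.22 (adjusted p = 1.56e-07, adjusted p = 0.422 with an estimated correlation). Ribosome biogenesis had 18 of 18, Mrto4 by 2.85 ± 0.15 (adjusted p = 1.16e-07, adjusted p = 0.0887 with an estimated correlation). Nucleotide and one-carbon synthesis had 16 of 17, Shmt1 by 4.97 ± 0.29 (adjusted p = 4.9e-06, adjusted p = 0.0887 with an estimated correlation). Chaperones had 12 higher, Sdf2l1 by 3.01 ± 0.20, and 1 lower of 15 (adjusted p = 0.000789, adjusted p = 0.26 with an estimated correlation). Glycolysis had 8 higher, Hk2 by 5.63 ± 0.18, and 1 lower of 12 (adjusted p = 0.0169, adjusted p = 0.534 with an estimated correlation). The citric acid cycle list had 13 higher, Fh1 by 1.82 ± 0.13, and 2 lower of 21 (adjusted p = 0.00913, adjusted p = 0.423 with an estimated correlation). Both of the last calls were lost with cyclic loess (adjusted p = 0.0666 and 0.154). With adjustment inside each list, 27, 17, 18, 16, 12, 8 and 13 genes were higher in these lists.

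Quiescence genes fell in 13 of 16 cases in IRL cells, Klf3 at -4.29 ± 0.19 (adjusted p = 2.65e-05, adjusted p = 0.247 with an estimated correlation). CD8 identity genes fell in 11 of 11 cases, Cd3g at -2.40 ± 0.18 (adjusted p = 0.000542, adjusted p = 0.423 with an estimated correlation). Homing receptors fell in 8 of 12 cases, with Itgb7 (-4.60 ± 0.17) and the sphingosine receptor gene S1pr4 (-4.28 ± 0.18), and rose in 1 (adjusted p = 0.0268, adjusted p = 0.534 with an estimated correlation). Interferon gamma and antigen processing genes fell in 12 of 16 cases, Irf1 at -2.28 ± 0.24, with Irf8 the 1 gene that rose (4.45 ± 0.31). That list had adjusted p = 0.00774, and adjusted p = 0.532 with an estimated correlation. Of 26 type I interferon genes 14 fell, such as Ddx58 (-4.06 ± 0.50), Oas2 (at least 4.63-fold) and Ifit3 (-2.66 ± 0.82, adjusted p = 0.0234). In the same list 1 rose (list adjusted p = 0.0127, adjusted p = 0.703 with an estimated correlation). Adjusted over the list alone, 13, 11, 8, 12 and 14 genes were lower in these 5 lists. The interferon list call was lost without IRL array 1 (adjusted p = 0.0594), and the Ifit3 call with the period as a block (adjusted p = 0.0722) and without naive array 1 or 2 or IRL array 1 (adjusted p up to 0.123).

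Lists that did not pass in IRL cells were effector molecules (8 higher, 6 lower of 16, with 9 and 6 over the list alone, adjusted p = 0.414), activation receptors (6 and 2 of 14, adjusted p = 0.176) and inhibitory receptors, where Lag3 was higher (at least 30.5-fold) and Dgka lower (-4.99 ± 0.25; 7 and 3 of 14, with 7 and 4 over the list alone, adjusted p = 0.693). The same held for early response genes (6 and 6 of 20, adjusted p = 0.876), effector transcription factors (6 and 7 of 19, adjusted p = 0.939; median -0.15, or 0 with undetected genes at their bound, and mean 0.02), apoptosis (5 and 5 of 15, with 6 and 5 over the list alone, adjusted p = 0.665), amino acid transport (5 and 1 of 7, adjusted p = 0.12) and lipid synthesis (6 and 2 of 13, with 7 and 3 over the list alone, adjusted p = 0.261). Dendritic cell and macrophage markers had 3 of 10 genes lower (adjusted p = 0.167), B cell markers 1 higher and 2 lower of 7 (1 and 1 over the list alone, adjusted p = 0.77), and neutrophil markers 0 of 8 (adjusted p = 0.876).

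Live LM was compared with naive to see what live bacteria changed. Ifng rose 830.4-fold in live LM cells (9.70 ± 0.30, adjusted p = 1.54e-06), and Il2 and Il3, which encode T cell cytokines, at least 69.7-fold and 68.2-fold. All 27 DNA replication genes and 17 of 18 mitosis genes rose, and 15 of 16 quiescence genes fell, Klf2 197-fold (-7.62 ± 0.48, adjusted p = 1.25e-05). Prf1, lower than naive in HKL and IRL, rose by 1.77 ± 0.36 (adjusted p = 0.00348). Of the genes tested 5190 (65.0%) passed, 2558 higher and 2632 lower, 3195 of them by at least 2-fold. The groups' arrays did not overlap for 6486 genes (81.3%, chance 33.3%).

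Ifng had the largest measured rise in live LM cells, and Zbtb32 rose at least 395-fold and Ccl3 at least 172-fold. The largest measured falls were in Klf2 and Hsd11b1 (-6.61 ± 0.30), while Fcgrt fell at least 80.6-fold, Ramp1, which encodes a subunit of a neuropeptide receptor, at least 60.3-fold and Scml4 at least 49.8-fold. Their adjusted p was at most 1.25e-05. Il2ra (at least 68.1-fold), Irf4 (4.88 ± 0.14), Tbx21 (3.67 ± 0.31), Myc (2.36 ± 0.28), Pdcd1 (2.29 ± 0.21) and Tnf (1.53 ± 0.34) rose and Il7r fell (-4.73 ± 0.50). The highest adjusted p of these genes was 0.00519. Eomes (0.19 ± 0.30, adjusted p = 0.587), Cxcr3 (-0.33 ± 0.43, adjusted p = 0.524) and Cd69 (-0.39 ± 0.30, adjusted p = 0.284) did not pass. With the period as a block, which here rests on the HKL and IRL arrays because naive and live LM share no period, the calls of Tnf (adjusted p = 0.0762) and Prf1 (adjusted p = 0.0614) were lost. Without naive array 1 the Tnf value was 0.99, and it still passed.

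By list, live LM cells had 27 of 27 DNA replication genes higher, Rrm2 at least 74.0-fold (camera adjusted p = 1.23e-13, adjusted p = 0.0887 with an estimated correlation). Of 18 mitosis genes 17 rose, Cdk1 at least 82.0-fold and Birc5 by 6.66 ± 0.22 (adjusted p = 3.19e-08, adjusted p = 0.415 with an estimated correlation). Ribosome biogenesis genes rose in 18 of 18 cases, Nolc1 by 2.98 ± 0.25 (adjusted p = 1.99e-07, adjusted p = 0.0887 with an estimated correlation). Nucleotide and one-carbon genes rose in 16 of 17, Shmt1 by 4.88 ± 0.29, with 1 lower (adjusted p = 4.9e-06, adjusted p = 0.0887 with an estimated correlation). Chaperones rose in 12 of 15 cases, Sdf2l1 by 3.24 ± 0.20, with 1 lower (adjusted p = 0.000283, adjusted p = 0.247 with an estimated correlation). Glycolysis genes rose in 9 of 12, Hk2 by 6.32 ± 0.18, with 1 lower (adjusted p = 0.00785, adjusted p = 0.532 with an estimated correlation). Citric acid cycle genes rose in 13 of 21, Fh1 by 1.64 ± 0.13, with 1 lower (adjusted p = 0.0093, adjusted p = 0.423 with an estimated correlation). The citric acid cycle call was lost with cyclic loess (adjusted p = 0.123). Within each list alone, 27, 17, 18, 16, 12, 9 and 13 genes were higher.

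Quiescence genes fell in 15 of 16 cases in live LM cells, Pik3ip1 at least 49.7-fold and Klf3 at -5.45 ± 0.19 (adjusted p = 2.38e-05, adjusted p = 0.247 with an estimated correlation). All 11 CD8 identity genes fell, Cd3g at -2.71 ± 0.18 (adjusted p = 0.000587, adjusted p = 0.423 with an estimated correlation). Of 12 homing receptors 9 fell, Itgae at -5.97 ± 0.53, and 1 rose (2 over the list alone, adjusted p = 0.0142, adjusted p = 0.532 with an estimated correlation). Interferon gamma and antigen processing genes fell in 10 of 16 cases, Irf1 at -2.21 ± 0.24, while Irf8 rose (4.92 ± 0.31). This list had adjusted p = 0.026, adjusted p = 0.534 with an estimated correlation and 0.0737 with 75th percentile scaling. With adjustment inside each list, 15, 11, 9 and 10 genes were lower in these 4 lists. Type I interferon genes fell in 7 of 26 cases (5 adjusted over the list alone), Ddx58 at -3.18 ± 0.50, with Bst2 higher (2.09 ± 0.34), and the list did not pass (adjusted p = 0.25). Effector molecules had 9 higher and 4 lower of 16 (adjusted p = 0.0546), activation receptors 6 higher, Tnfrsf4 by 4.50 ± 0.23, and 2 lower of 14 (adjusted p = 0.118). Inhibitory receptors had 7 higher, such as Lag3 (at least 56.2-fold) and Ctla4 (3.68 ± 0.74), and 4 lower, such as Dgka (-5.73 ± 0.25), of 14 (7 and 5 over the list alone, adjusted p = 0.61). Early response genes (6 higher, 6 lower of 20, adjusted p = 0.855), effector transcription factors (9 and 5 of 19, adjusted p = 0.272) did not pass either, nor did apoptosis (4 and 4 of 15, adjusted p = 0.738), amino acid transport (4 and 1 of 7, with 5 and 1 over the list alone, adjusted p = 0.112) and lipid synthesis (6 and 4 of 13, adjusted p = 0.43).

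Markers of other cells also moved in live LM cells. Of 8 neutrophil markers 4 were higher than naive, S100a8 by 3.78 ± 1.15 (adjusted p = 0.0218), S100a9 9.57-fold (adjusted p = 0.0228), Lcn2 at least 4.57-fold (adjusted p = 3e-04) and Retnlg by 2.03 ± 0.48 (adjusted p = 0.00709). The list did not pass (adjusted p = 0.078). Of 10 dendritic cell and macrophage markers 2 were higher, such as Fcer1g, a signalling chain of Fc receptors (1.90 ± 0.53, adjusted p = 0.0147), and 2 lower (list adjusted p = 0.986; median 0.03 and mean 0.17, while the test ran toward lower values). Of 7 B cell markers 1 was higher and 1 lower (0 and 1 over the list alone, adjusted p = 0.908). Without naive array 1 the calls of S100a8 (2.63, adjusted p = 0.124), S100a9 (2.71, adjusted p = 0.11) and Fcer1g (1.30, adjusted p = 0.084) were lost. They were also lost without either live LM array, and that of Retnlg without live LM array 2 (1.65, adjusted p = 0.0534). With the period as a block none of these 4 passed (adjusted p = 0.267, 0.3, 0.194 and 0.11). Lcn2 passed in each of these fits.

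**Figure D2:**
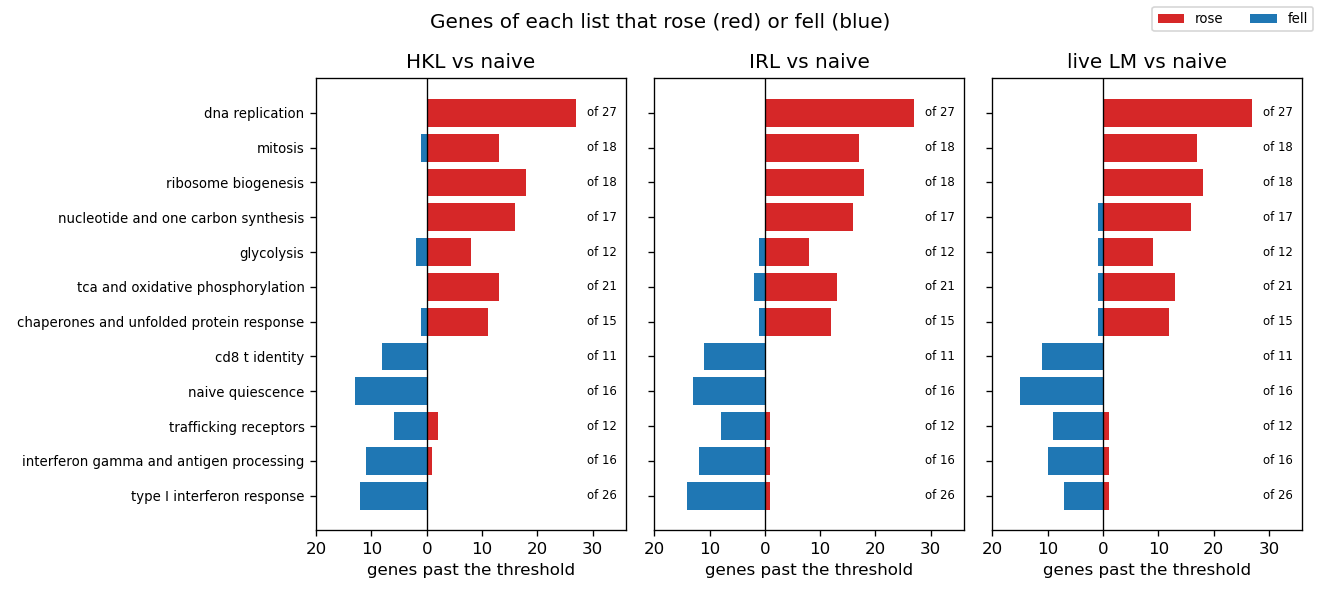
Number of genes past the threshold that rose (red, to the right) or fell (blue, to the left) in 12 of the fixed lists, for each comparison with naive, with the number tested at the right of each bar. All 27 DNA replication and all 18 ribosome biogenesis genes rose in each comparison, and 13, 13 and 15 of 16 quiescence genes fell.

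Most of the change from naive was common to the immunized groups. Of the 5812 genes that differed from naive in at least 1 comparison, 4236 differed in the same direction in all 3, 2099 higher and 2137 lower, where independent lists would share 240 and 255. The growth genes Rrm2, Cdk1 and Hk2 and the cytokine genes Ifng and Il2 were among those higher in each comparison, and Klf2, Il7r and Fcgrt among those lower. HKL and IRL shared 2229 higher and 2266 lower genes (independent lists 750 and 775) and none of opposite direction. HKL and live LM shared 2141 and 2209 (755 and 805) with 12 opposite, and IRL and live LM 2291 and 2334 (814 and 835) with 9 opposite. Across genes, the log2 fold changes correlated with r = 0.977, 0.944 and 0.962 in these pairs, with covariances of 1.90, 1.95 and 2.18. Since the comparisons share the naive arrays, 20 sets of unchanged groups were simulated against them. These gave r = 0.503, 0.498 and 0.504, covariances of 0.0289, 0.0286 and 0.0292, and at most 1 shared gene. The naive arrays cannot be split with at least 2 in each part, so part of the excess over independent lists may come from the shared arrays.

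Live LM was then compared with HKL to see how the response to live bacteria differed from that to killed ones. Live LM cells had 68.7-fold more Il3 (6.10 ± 0.20, adjusted p = 4.55e-05), 8.36-fold more Ifng (3.06 ± 0.30, adjusted p = 0.00269), 6.30-fold more Il2 (2.66 ± 0.25, adjusted p = 0.00247) and 9.27-fold more Prf1 (3.21 ± 0.36, adjusted p = 0.0047). Il3 lay just above the detection floor on both HKL arrays, so its fold depends on that floor. Il10, an anti-inflammatory cytokine gene, was at least 44.5-fold higher (adjusted p = 0.00105). The receptor genes Il2ra (2.53 ± 0.14, adjusted p = 0.000589) and Tnfrsf4, which encodes OX40 (3.34 ± 0.23, adjusted p = 0.000791), were also higher. Of the genes tested 516 (6.46%) passed, 263 higher and 253 lower in live LM, 291 of them by at least 2-fold. In a separate fit of the 5089 genes detected on all 8 arrays, 177 were higher and 316 lower, with 278 of the 516 among them. This filter leaves out genes undetected in a group, so the 2 balances are not over the same genes. For 4778 genes (59.9%) the arrays did not overlap, where chance gives 33.3%.

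**Figure D3:**
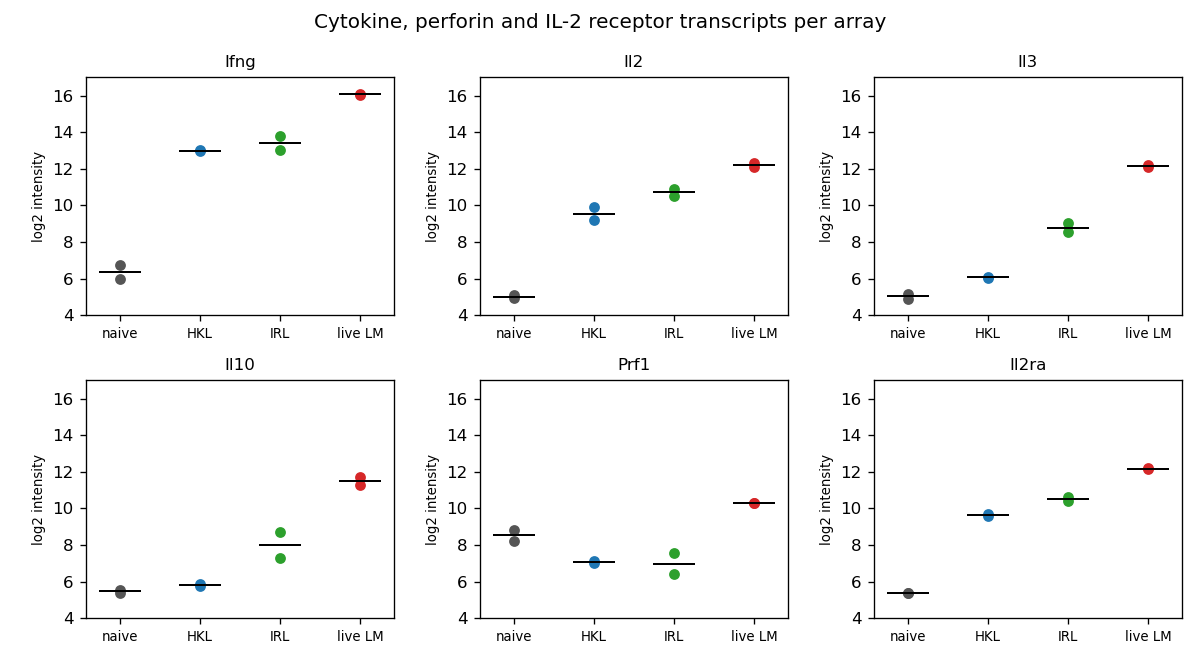
Log2 intensity of 6 genes on each array (points) with the mean of each group (line). Il3, Il10, Ifng, Il2 and Il2ra were highest on both live LM arrays, and Prf1 was above 10 on both live LM arrays and below 9 on all others.

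After Il3, the largest measured rise was in Timp1, an inhibitor of metalloproteinases (4.54 ± 0.29), while Sdcbp2 rose at least 13.2-fold and the cytokine gene Il17f at least 8.33-fold. The largest measured falls were in Trat1, an adaptor of the T cell receptor (-2.67 ± 0.22), and Sfxn3 (-2.56 ± 0.23), while the thromboxane receptor gene Tbxa2r fell at least 5.64-fold, Ramp1 at least 5.27-fold and the phosphatase gene Inpp4b at least 3.49-fold. The highest adjusted p of these genes was 0.00753. The transcription factor genes moved apart, with Tbx21 higher (1.41 ± 0.31, adjusted p = 0.0413) and Eomes lower (-1.91 ± 0.30, adjusted p = 0.0147), and Pdcd1 was higher (1.23 ± 0.21, adjusted p = 0.0198). The Tbx21 call was lost with the period as a block (adjusted p = 0.123), with the class II score (0.0881) and in 6 of the 8 fits without 1 array, and the Pdcd1 call with the block (0.0712). Tnf (0.91 ± 0.34, adjusted p = 0.171), Il7r (1.52 ± 0.50, adjusted p = 0.134), Cxcr3 (-1.11 ± 0.43, adjusted p = 0.187), Cd69 (-0.49 ± 0.30, adjusted p = 0.397), Myc (-0.40 ± 0.28, adjusted p = 0.464) and Irf4 (-0.02 ± 0.14, adjusted p = 0.952) did not pass. With the period as a block Il7r passed as higher in live LM (2.13, adjusted p = 0.0147).

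Mitosis genes were higher in live LM than in HKL cells in 10 of 18 cases (16 adjusted over the list alone), with the centromere gene Cenpa at 2.26 ± 0.36, the kinase gene Plk1 at 2.16 ± 0.36, Ube2c at least 2.63-fold and Cdc20 at 1.85 ± 0.35 (camera adjusted p = 3.02e-12, adjusted p = 0.26 with an estimated correlation). Of 19 effector transcription factors and cytokine signalling genes 8 rose and 1 fell (10 and 1 over the list alone), including the receptor genes Il12rb2 (2.44 ± 0.37) and Il18r1 (1.85 ± 0.23). The list had adjusted p = 3.03e-05, and adjusted p = 0.0946 with an estimated correlation. Of 16 effector molecules 5 rose, such as Prf1, Ifng, Il2 and Ccl3 (2.22 ± 0.29), and 2 fell (8 and 2 over the list alone). The list had adjusted p = 0.00455, and adjusted p = 0.247 with an estimated correlation. Homing receptors were lower in 3 of 12 cases (4 over the list alone), all of them integrin chain genes: Itgb2 (-1.08 ± 0.18), Itgb7 (-0.85 ± 0.17) and Itgal (-0.80 ± 0.14). With the period as a block the calls of Itgb7 (adjusted p = 0.101) and Itgal (0.0731) were lost, as with the class II score (0.0795 and 0.0576). For homing receptors adjusted p = 0.000279, and adjusted p = 0.423 with an estimated correlation. Quiescence genes were lower in 2 of 16 cases, Klf3 (-1.81 ± 0.19) and Tgfbr2 (-0.93 ± 0.20), and over the list alone 8 were lower and 1 higher. For quiescence adjusted p = 0.00774, and adjusted p = 0.423 with an estimated correlation. DNA replication genes rose in 2 of 27 cases, also over the list alone (list adjusted p = 0.0481, adjusted p = 0.499 with an estimated correlation). This call was lost without HKL array 2 (adjusted p = 0.22), IRL array 1 (0.053), live LM array 1 (0.0582) or live LM array 2 (0.0725). CD8 identity genes fell in 1 of 11 cases, Cd3g (-0.97 ± 0.18), and in 6 over the list alone. The list had adjusted p = 0.0289, and adjusted p = 0.534 with an estimated correlation. Its call was lost without HKL array 1 (adjusted p = 0.0863), without live LM array 2 (0.119), with the period block (0.0791), with the class II score (0.0558) and with both other scalings (0.0549 and 0.0539). The gene calls of Cdc20 (adjusted p = 0.0743 and 0.0639), Tgfbr2 (0.111 and 0.0900) and Cd3g (0.0755 and 0.0566) were also lost with the period block and with the score.

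Type I interferon genes were higher in 2 of 26 cases in live LM than in HKL cells. These were the sensor gene Zbp1 (at least 3.46-fold) and, close to the threshold, the tetherin gene Bst2 (1.46 ± 0.34, adjusted p = 0.0494). With an array left out the Bst2 value ran from 1.01 to 1.92. The list had adjusted p = 0.0121, and adjusted p = 0.703 with an estimated correlation. Without HKL array 2 the list's shift turned from 0.46 to -0.42 (adjusted p = 0.0642), and among the later arrays alone it was 1.34. With the period block the calls of Zbp1 (adjusted p = 0.0547), Bst2 (0.0977) and Cd27 (0.0624) were lost. Activation receptors had 4 genes higher, with Tnfrsf18 at 1.05 ± 0.23, and 1 lower, Cd27 (-0.87 ± 0.14), of 14 (list adjusted p = 0.209). Inhibitory receptors had 2 higher, with Nrp1 at 2.47 ± 0.31, and 3 lower of 14 (2 and 4 over the list alone, list adjusted p = 0.97). Among 20 early response genes 2 were higher (4 higher and 1 lower over the list alone, adjusted p = 0.939), and 1 of 16 interferon gamma response genes was higher (adjusted p = 0.388), as were 1 of 12 glycolysis (2 over the list alone, adjusted p = 0.0616) and 1 of 7 amino acid transport genes (adjusted p = 0.397). Medians and means differed in sign for the inhibitory (-0.11 and 0.12) and early response lists (-0.30 and 0.02), with medians of -0.02 and -0.14 when undetected genes were taken at their bound. For the inhibitory and early response lists the test ran toward lower values. None of the tested genes passed in apoptosis (0 of 15, adjusted p = 0.457), chaperones (0 of 15, adjusted p = 0.0952), lipid synthesis (0 of 13, adjusted p = 0.346), nucleotide synthesis (0 of 17, adjusted p = 0.958), ribosome biogenesis (0 of 18, adjusted p = 0.684) or the citric acid cycle (0 of 21, adjusted p = 0.421).

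Myeloid markers moved with these gene groups. Neutrophil markers were higher in live LM than in HKL in 1 of 8 cases, Lcn2 (2.30 ± 0.36, detected on 1 of the 2 HKL arrays, as was Fcer1g), and in 2 over the list alone (list adjusted p = 0.00199, and adjusted p = 0.532 with an estimated correlation). The same held for 1 of 10 dendritic cell and macrophage markers, Fcer1g (2.32 ± 0.53, adjusted p = 0.0472, list adjusted p = 0.1), with 1 of 7 B cell markers lower (list adjusted p = 0.464). The shift of the neutrophil list was 0.57 among the later arrays alone, below its value over all arrays. That of the dendritic cell and macrophage list was 0.89 over all arrays and -0.10 among the later ones. With the period as a block 233 genes differed between live LM and HKL, and 267 with the class II score as a covariate, both chosen after seeing the data. Of the 516 genes, 216 and 258 were among them. The count was 104 without HKL array 1, 228 without HKL array 2, 89 without live LM array 1 and 66 without live LM array 2. Of 38 named genes that passed, 27 passed with the block, which ended the call of Fcer1g too (adjusted p = 0.131), and 32 with the score. Of the 38, 14 passed in each of the 8 fits without 1 array, namely Il3, Il10, Timp1, Il17f, Tbxa2r, Trat1, Ramp1, Sfxn3, Inpp4b, Ifng, Il2, Il2ra, Klf3 and Tnfrsf4. For the others the adjusted p reached at most 0.263. All 38 kept their direction among the later arrays alone. Those arrays also made the calls, so the direction was largely fixed in advance and says little about the period.

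Live LM was compared with IRL to see how live bacteria differed from irradiated ones. Live LM cells had 9.95-fold more Prf1 (3.32 ± 0.36, adjusted p = 0.00896), 6.30-fold more Ifng (2.66 ± 0.30, adjusted p = 0.0101), 3.18-fold more Il2ra (1.67 ± 0.14, adjusted p = 0.00288) and 2.81-fold more Il2 (1.49 ± 0.25, adjusted p = 0.0413). Il10 was 11.3-fold higher (3.49 ± 0.42, adjusted p = 0.0129) and Il17f at least 7.44-fold (adjusted p = 0.000152). With an array left out the Il10 value ran from 2.77 to 4.22. Of the genes tested 106 (1.33%) passed, 76 higher and 30 lower in live LM, 83 of them by at least 2-fold. In the separate fit of genes detected on all 8 arrays the balance turned, with 21 higher and 30 lower. The arrays of 3841 genes (48.1%, chance 33.3%) did not overlap.

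The largest measured rises over IRL were in Timp1 (4.16 ± 0.29, adjusted p = 0.00137), the inflammatory cytokine gene Il1b (3.50 ± 0.61, adjusted p = 0.0481), which was detected on 1 of the 2 IRL arrays, and Il10. The protease inhibitor gene Slpi rose at least 7.31-fold (adjusted p = 0.0344). The largest measured falls were in Med14, a Mediator subunit (-2.09 ± 0.29), the myosin light chain gene Myl4 (-2.06 ± 0.18), the adhesion receptor gene Cd226 (-1.91 ± 0.18), Trat1 (-1.85 ± 0.22) and the transcription factor gene Gata3 (-1.79 ± 0.28), with Med14, Myl4 and Gata3 detected on 1 of the 2 live LM arrays. The highest adjusted p of these genes was 0.0344. The calls of Il1b (adjusted p = 0.138), Slpi (0.0602), Med14 (0.0528) and Gata3 (0.0664) were lost with the period as a block, and with the class II score those of Il1b (0.0795), Med14 (0.0663), Gata3 (0.104) and Il2 (0.0625). Tbx21 (2.30-fold higher, adjusted p = 0.138), Eomes (-1.09 ± 0.30, adjusted p = 0.163), Pdcd1 (0.93 ± 0.21, adjusted p = 0.102), Il7r (0.97 ± 0.50, adjusted p = 0.45), Tnf (0.62 ± 0.34, adjusted p = 0.467), Cxcr3 (-1.06 ± 0.43, adjusted p = 0.337), Cd69 (-0.55 ± 0.30, adjusted p = 0.46), Myc (0.28 ± 0.28, adjusted p = 0.726) and Irf4 (0.06 ± 0.14, adjusted p = 0.909) did not pass.

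Effector molecules were higher in live LM than IRL in 5 of 16 cases (8 higher and 2 lower over the list alone), with Ccl3 at 2.12 ± 0.29 beside Prf1, Ifng and Il2 (camera adjusted p = 2.56e-06, adjusted p = 0.0887 with an estimated correlation). Effector transcription factors and cytokine signalling genes rose in 3 of 19 cases (8 higher and 1 lower over the list alone): the interleukin-18 receptor genes Il18r1 (2.09 ± 0.23) and Il18rap (at least 1.29-fold), and Bcl3 (1.68 ± 0.24). The list had adjusted p = 9.9e-05, and adjusted p = 0.108 with an estimated correlation. Tnfrsf4 (1.88 ± 0.23) and Il2ra were the 2 of 14 activation receptor genes that rose (4 higher and 1 lower over the list alone, list adjusted p = 0.0379, and adjusted p = 0.534 with an estimated correlation). This list call was lost without IRL array 2 (adjusted p = 0.246), live LM array 1 (0.0503) or live LM array 2 (0.0526) and with both other scalings (0.122 and 0.0831). Klf3 fell by 1.16 ± 0.19 (adjusted p = 0.035), the 1 of 16 quiescence genes past the threshold, also over the list alone (list adjusted p = 0.0776). With the period block the calls of Klf3 (adjusted p = 0.126) and Ccl3 (0.0643) were lost, and with the class II score those of Klf3 (0.115) and Bcl3 (0.0726).

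Several lists shifted as a whole from IRL to live LM with 0 genes past the threshold, also over the list alone. These were type I interferon genes (0 of 26, adjusted p = 2.56e-06, adjusted p = 0.534 with an estimated correlation), mitosis (0 of 18, adjusted p = 0.000107, adjusted p = 0.481 with an estimated correlation), the interferon gamma response (0 of 16, adjusted p = 0.00881, adjusted p = 0.532 with an estimated correlation), glycolysis (0 of 12, adjusted p = 0.0255, adjusted p = 0.543 with an estimated correlation) and chaperones (0 of 15, adjusted p = 0.0256, adjusted p = 0.423 with an estimated correlation), all toward higher values. Without IRL array 1 the mitosis (adjusted p = 0.37), interferon gamma (0.151) and glycolysis (0.0595) calls were lost, and the mitosis shift went from 0.44 to 0.12. The glycolysis call was also lost without IRL array 2 (0.0632) or live LM array 2 (0.0978) and with 75th percentile scaling (0.0792). The chaperone call was lost without IRL array 2 (0.258) or live LM array 1 (0.0566) and with the class II score (0.0926). Other lists did not pass: CD8 identity (adjusted p = 0.899), early response (0.84), inhibitory receptors (0.81), apoptosis (0.81), amino acid transport (0.478), DNA replication (0.142), ribosome biogenesis (0.272), nucleotide synthesis (0.553), citric acid cycle (0.939), lipid synthesis (0.665) and homing receptors (0.209), with 0 of their genes past the threshold. Over the list alone 2 inhibitory receptor genes were higher and 1 lower, and 1 early response gene was lower. The median and mean differed in sign for apoptosis (0.01 and -0.07) and inhibitory receptors (-0.08, or -0.04 with undetected genes at their bound, and 0.08), and for the citric acid cycle and early response lists both were negative while the test ran toward higher values.

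Myeloid markers were again higher on the live LM arrays. Of 8 neutrophil markers 1 rose over IRL, Lcn2 (at least 4.27-fold, adjusted p = 0.0143), and 6 over the list alone (list adjusted p = 5.11e-07, adjusted p = 0.423 with an estimated correlation). Of 10 dendritic cell and macrophage markers 1 rose, Fcer1g (at least 4.32-fold, adjusted p = 0.044), and 2 over the list alone (list adjusted p = 0.000144, adjusted p = 0.423 with an estimated correlation), while 0 of 7 B cell markers passed (list adjusted p = 0.6). Among the later arrays alone the shifts were 2.15 for neutrophil and 1.17 for dendritic cell and macrophage markers, against 2.12 and 1.39 over all arrays. With the period as a block 64 genes differed, 55 of them among the 106, and likewise 64 and 55 with the class II score. Without IRL array 1 the count was 24, without IRL array 2 it was 54, without live LM array 1 it was 15 and without live LM array 2 it was 17. Of the 22 named genes that passed, 15 passed with the block, which ended the call of Fcer1g too (adjusted p = 0.124), and 16 with the score. Timp1, Il17f, Il2ra and Myl4 passed in each of the 8 fits without 1 array, and for the others the adjusted p reached at most 0.29. All 22 kept their direction among the later arrays alone, which again were among the arrays that made the calls.

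**Figure D4:**
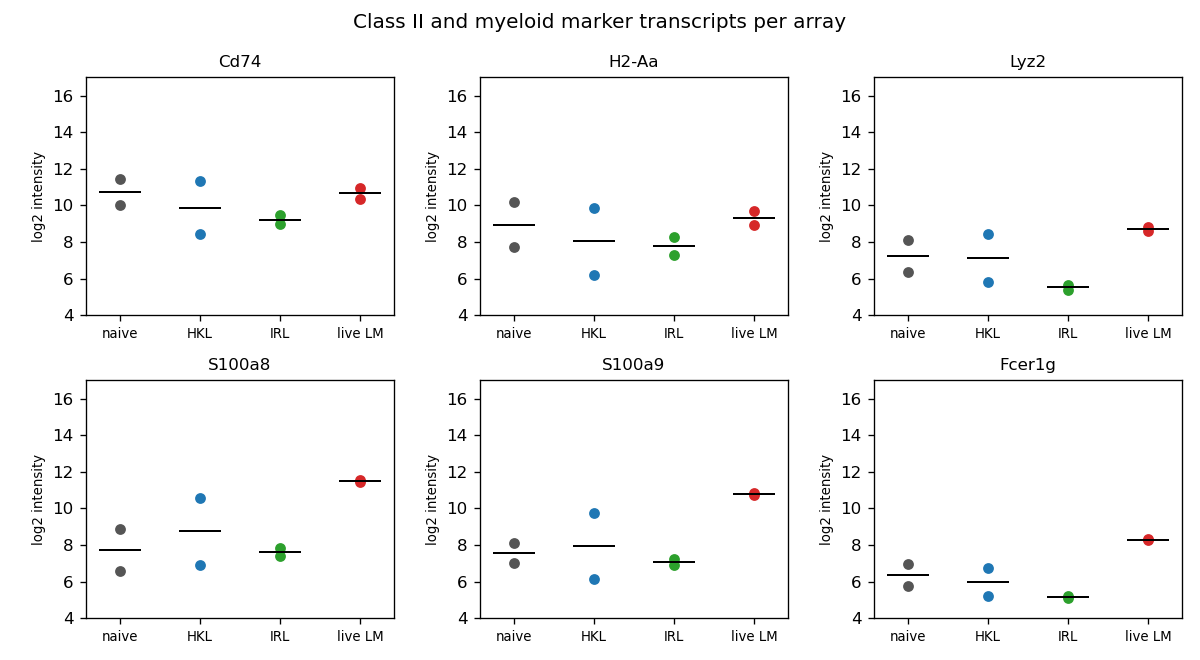
Log2 intensity of class II and myeloid marker transcripts on each array (points) with the mean of each group (line). S100a8, S100a9 and Fcer1g were highest on both live LM arrays, and HKL array 2 lay above HKL array 1 for each of the 6 genes.

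IRL was compared with HKL to see whether irradiated and heat-killed bacteria differed. Il3, which lay just above the detection floor on both HKL arrays, was 6.55-fold higher in IRL cells (2.71 ± 0.20, adjusted p = 0.0147). Sema4a, a semaphorin gene, was 3.14-fold lower (-1.65 ± 0.16, adjusted p = 0.0491). These were the 2 of 7982 genes (0.0251%) that passed, with 798 genes at an unadjusted p under 0.05, and the arrays of 3645 genes (45.7%, chance 33.3%) did not overlap. Il2 (1.17 ± 0.25, adjusted p = 0.263), Il2ra (0.86 ± 0.14, adjusted p = 0.173), Eomes (-0.82 ± 0.30, adjusted p = 0.418), Myc (-0.68 ± 0.28, adjusted p = 0.471), Il7r (0.55 ± 0.50, adjusted p = 0.77), Ifng (0.41 ± 0.30, adjusted p = 0.699), Pdcd1 (0.29 ± 0.21, adjusted p = 0.695), Tnf (0.29 ± 0.34, adjusted p = 0.834), Tbx21 (0.21 ± 0.31, adjusted p = 0.881), Prf1 (-0.10 ± 0.36, adjusted p = 0.948), Irf4 (-0.08 ± 0.14, adjusted p = 0.903), Cd69 (0.07 ± 0.30, adjusted p = 0.959) and Cxcr3 (-0.05 ± 0.43, adjusted p = 0.978) did not pass. The Sema4a call was lost in each of the 8 fits without 1 array (adjusted p up to 0.415), with the period block (0.0838) and with the class II score (0.172). The Il3 call was lost without either HKL array, IRL array 1 or either live LM array, with values from 2.46 to 2.96 over the fits without 1 array. It was also lost with cyclic loess, with 75th percentile scaling and with only the 2 groups compared. It passed with the block (adjusted p = 0.04) and the score (adjusted p = 0.0465).

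As a list, mitosis genes were higher in IRL than in HKL cells, with 0 of 18 past the threshold over all genes and 14 over the list alone (camera adjusted p = 6.76e-11, adjusted p = 0.288 with an estimated correlation). The shift was 0.82 over all arrays and 1.12 among the later arrays alone. CD8 identity genes (0 of 11, adjusted p = 0.000364, adjusted p = 0.423 with an estimated correlation), homing receptors (0 of 12, 2 lower over the list alone, adjusted p = 0.000492, adjusted p = 0.423 with an estimated correlation) and quiescence genes (0 of 16, adjusted p = 0.0343, adjusted p = 0.481 with an estimated correlation) were lower as lists. The quiescence call was lost without HKL array 1 (adjusted p = 0.0561), HKL array 2 (0.0689) or IRL array 2 (0.802). Dendritic cell and macrophage markers (0 of 10, adjusted p = 0.0333, adjusted p = 0.593 with an estimated correlation) and neutrophil markers (0 of 8, adjusted p = 0.047, adjusted p = 0.654 with an estimated correlation) were lower in IRL as lists. Without HKL array 2 their shifts turned from -0.51 to 0.48 (adjusted p = 0.542) and from -0.62 to 0.31 (adjusted p = 0.189). The neutrophil call was also lost without naive array 1 or 2 (0.0829), IRL array 1 (0.173) or IRL array 2 (0.0842). Lost too was the dendritic cell and macrophage call without IRL array 1 (0.261). With cyclic loess neither passed (0.106 and 0.0562). Type I interferon genes did not pass (adjusted p = 0.167), with a shift of -0.32 over all arrays and 0.77 among the later arrays alone, nor did the other lists, with adjusted p from 0.0503 for B cell markers to 0.946 for early response genes. Over the list alone, activation receptors had 3 higher and 2 lower, inhibitory receptors 2 and 2, effector molecules 1 and 4 and effector transcription factors 1 and 0. The median and mean were -0.15 (-0.09 with undetected genes at their bound) and 0.04 for inhibitory receptors and differed in sign for chaperones too, with both tests toward lower values.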

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

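All tests in this part were chosen only after the results were seen, except the one on Il1b, Slpi and Fpr2, which was written before its result.

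Probes without a gene name in the probe table used here took no part in the comparisons of genes. Of the 1423 of them that were kept, 374 were higher and 396 lower in live LM than in naive cells, 329 and 356 in HKL, and 345 and 382 in IRL. Between live LM and HKL 18 were higher and 9 lower, and none passed between live LM and IRL or between IRL and HKL. What singled them out is a signal in data that the comparisons of genes do not use.

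Live LM arrays are all from the later period, so the difference from HKL and IRL was weighed against the period. Over 581 genes that differed by at least 1 log2 unit between live LM array 1 and HKL array 1, the difference between the later arrays alone was a median of 0.748 of that value (quartiles 0.47 and 0.956), in the same direction for 533, which argues against the period as the whole cause. For live LM and IRL the median was 0.505 over 386 genes (quartiles 0.199 and 0.856), in the same direction for 326, where the difference between the naive arrays, of the same period, agreed for at most 195; the directions are more alike than that difference gave, but the lower quartile lies in the range set for the period, so its share stays open. With the period as a block 216 of 516 and 55 of 106 genes still passed, with median ratios of the log2 fold changes of 0.952 and 0.973 and median standard errors going from 0.191 to 0.204 and from 0.198 to 0.219, and the period term itself passed for 0 genes. An effect of live bacteria on the T cells stays open as a hypothesis, beside a part played by the period.

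Myeloid transcripts were higher on the live LM arrays, and RNA of other cells in the sorted population could bring them. Il1b, Slpi and Fpr2, in none of the fixed lists, were higher on HKL array 2 than on HKL array 1 by 2.14, 1.83 and 0.658 (median 1.83), as were 17 of 18 myeloid markers, so that these transcripts varied together within a group that received the same bacteria. Between the IRL arrays the markers' median difference was 0.0164. Of the 13 effector genes called higher in live LM than in HKL, 10 still passed with the class II score as a covariate. Their log2 fold changes were a median of 0.996 of those without it (quartiles 0.95 and 1.05). The myeloid markers Fcer1g and Lcn2 also kept most of theirs, going from 2.32 to 1.81 and from 2.30 to 2.00. This fit therefore cannot tell transcripts of T cells from those of other cells, and class II-positive cells stay open as a source. The score does not measure neutrophils. The gate also required CD8 and the transfer marker CD45.1, the latter of which host myeloid cells would not be expected to carry. The way such RNA would enter stays open, as does a change in the T cells' own transcripts, which was not tested.

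Type I interferon transcripts differed between the HKL arrays: 25 of 26 were higher on array 1, by a median of 1.59 (quartiles 0.893 and 2.77). The period would be expected to shift the IRL arrays alike, but there the median was -0.294, which argues against it as the cause. Class II, macrophage and B cell markers were lower on HKL array 1, with a median of -1.53, which argues against RNA of those cells as the source. A difference between the mice or in the bacteria they received stays open and could not be tested with 1 array each. No biological explanation was tested, since the labels put both arrays in the same group.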

How the results depend on the processing

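The fits with the period block and the class II score, and the values within a period, were chosen only after the results were seen. No paired analysis was possible because the array numbers run from 1 to 8 with none shared between groups, and for the same reason the planned block of array number was not run. Leaving out an array leaves 1 in its group, which is assumed to vary like the other groups. With 2 arrays per group and 4 residual degrees of freedom, genes near the background are the least precise. Of the counts of genes under all alternatives, 95 stayed within 1.5 times the value given above and 37 moved further. Of the list calls 704 kept direction and threshold, 119 lost the threshold and 3 turned. Of the values of named genes 3591 kept direction and side of the threshold, 259 lost it, 14 gained it, and 27 turned, all of these in genes that had not passed; 185 are values without a test that moved. Against the processed values of the authors 87 named values were alike, 142 moved and 0 turned. For these values and those within a period, a turn was counted only for genes that had passed. Prf1 in IRL vs HKL, for example, went from -0.10 to 0.51 among the later arrays alone and was not counted as turned. Within the earlier period alone 74 were alike and 19 moved, and within the later one 66 and 24. The cause was not tested for any of the changes below, apart from the stricter filters, which keep fewer genes, and the left-out arrays.

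Requiring a fitted 2-fold change left 2929 genes for HKL, 3280 for IRL and 3371 for live LM against naive, and 319 for live LM vs HKL. For live LM vs HKL (516) the count was 233 with the period block, 267 with the class II score, 823 with only the 2 groups compared, 773 with trend and robust moderation, and between 66 and 652 with an array left out. For live LM vs IRL (106) it was 167 without background correction, 41 with 75th percentile scaling, 51 for genes detected on all 8 arrays, 217 with trend and robust moderation, 64 with the period block, 64 with the class II score, and between 15 and 118 with an array left out. For IRL vs HKL (2) it was 9 without background correction, 0 with cyclic loess, 0 with 75th percentile scaling, 1 for genes detected on all 8 arrays, 16 with trend and robust moderation, 0 with only the 2 groups compared, 1 with the period block, 1 with the class II score, and between 0 and 1 with an array left out. The 4236 changes shared by all 3 comparisons with naive stayed within 1.5 times that count under each alternative run. Scaling to the 75th percentile moved the median log2 fold change of all genes in HKL vs naive from -0.06 to -0.19.

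Of the 59 list calls 0 were kept with an estimated correlation, 42 with fry, 51 with cyclic loess, 55 with 75th percentile scaling, 57 with the period block and 57 with the class II score. Among all 138 list tests between 52 and 64 passed with an array left out. The type I interferon list in live LM vs HKL ran from -0.417 to 1.34 with an array left out, turning without HKL array 2. In IRL vs HKL the dendritic cell and macrophage list ran from -1.49 to 0.484 and the neutrophil list from -1.54 to 0.313, both turning without HKL array 2.

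None of the genes that turned had passed. Cd69 was -0.16 in HKL vs naive and -0.0748 in IRL vs naive with cyclic loess, and with an array left out it ran from -0.34 to 0.54 and from -0.27 to 0.61. In live LM vs naive Cd69 ran from -0.83 to 0.0526 and Eomes from -0.14 to 0.53, with Eomes at -0.12 under the period block. In live LM vs HKL Irf4 was 0.0371 with cyclic loess and 0.0726 with 75th percentile scaling and ran from -0.10 to 0.0571. In live LM vs IRL Irf4 was -0.0160 with 75th percentile scaling, -0.0185 with the period block and -0.0225 with the class II score, and ran from -0.0176 to 0.14, while Myc ran from -0.16 to 0.72. In IRL vs HKL, 75th percentile scaling gave 0.04999 for Cxcr3 and 0.0886 for Irf4. With an array left out, Cd69 ran from -0.15 to 0.29 there, Prf1 from -0.66 to 0.46, Tbx21 from -0.0160 to 0.44, Il7r from -0.25 to 1.36 and Cxcr3 from -0.67 to 0.56.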

Other observations

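The test in this part was chosen only after the result was seen.

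IRL arrays lay between those of HKL and live LM for some of the genes that set the latter apart. Il3 had log2 values of 6.03 and 6.12 on the HKL arrays, 9.03 and 8.53 on the IRL arrays and 12.12 and 12.23 on the live LM arrays, and Il10 had 5.77 and 5.89, 7.28 and 8.72, and 11.28 and 11.71. Il3 lay just above the detection floor of the HKL arrays (6.02 on each). Il10 was not detected on the HKL arrays, nor Il17f on those of HKL and IRL, so that Il17f has no order between them. Prf1 was not intermediate, with 7.15 and 7.03, 6.43 and 7.55, and 10.30 and 10.31. A hypothesis of an intermediate response to irradiated bacteria was tested over the 581 genes that differed by at least 1 log2 unit between live LM array 1 and HKL array 1, using only the other, later arrays. The slope of IRL minus HKL on live LM minus HKL was 0.368. In 100 simulated draws it lay between 0.0163 and 0.0959 with IRL equal to HKL, and between 0.892 and 0.974 with IRL equal to live LM. The slope, which describes the genes as a set and not each of them, thus lay outside both ranges, on 1 array per group. HKL array 2 enters both sides of it, so noise in that array alone could add to the slope, as the range for IRL equal to HKL shows. The simulated noise was independent between genes, so deviations that many genes of an array share would widen both ranges. Il3 and Il10 are themselves among the 581 genes. An intermediate response therefore stays a hypothesis.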
